A study of Homo sapiens with 9 samples.

How the data were processed

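Gene expression was measured in MCF-7 cells, an established estrogen receptor-positive human breast cancer line, on 9 Affymetrix oligonucleotide arrays. According to the labels' protocols, cells were held without serum in medium free of phenol red and then given vehicle or estradiol (E2). The arrays formed 3 groups of 3: vehicle for 3 h, E2 for 3 h and E2 for 6 h. The treatment protocol gives an E2 concentration that reads as 1 nM, while the series text writes it in a notation that can be read otherwise. No 6 h vehicle sample was analysed here, so the 3 h vehicle arrays served as the control for both E2 times.

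The deposited values are log2 expression values, 1 per probe set and array. RMA is named in the submitters' processing notes, and its software and version are not given in the sources used here. RMA as usually run gives all arrays of a run the same distribution of probe signals. The deposited arrays did not share 1 distribution: the SD over probe sets was 1.93 to 1.96 on the E2 3 h arrays and 1.81 to 1.88 on the others, and the 99th percentile ran from 12.1 (vehicle replicate 3) to 12.7 (E2 3 h replicate 3). The log2 scale was checked on the values: array medians lay between 7.24 and 7.28. No detection calls or scanner signals were used here, so a dim probe set could not be told from background, and the number of arrays limits the precision.

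The table holds 54675 probe sets, of which 62 are Affymetrix controls. A platform annotation named genes for 42898 of them. A single gene was named for 41091 probe sets and several genes for 1801, which were left unnamed. The 11721 probe sets outside the annotation are unnamed here. Entrez identifiers of 41037 probe sets were found in the RefSeq gene table, and 0 symbols changed through it. Each of 19775 genes was represented by its probe set with the highest mean over the 9 arrays. Several probe sets existed for 10523 genes. No filter on dim probe sets was applied. No genome build is named in the sources used here, so no coordinates are given.

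Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), in 1 fit of all 9 arrays with a mean per group. The residual degrees of freedom were 6 and the prior degrees of freedom 8.61. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 18 lists. Camera with an estimated correlation and fry were alternatives. Fry asks whether the genes of a list move on balance 1 way and does not compare them with other genes, so a shift of bright genes can pass it. Camera compares a list with all other genes, dim ones included, so such a shift can pass it too where a list is bright. The lists cover estrogen-induced and estrogen-repressed genes, immediate early genes, G1/S and replication genes, G2/M and mitosis genes, ribosome biogenesis, antiproliferative and cell death genes, growth factors and receptors, nuclear receptors and coregulators, sterol and fatty acid synthesis, the unfolded protein response with amino acid starvation, heat shock, hypoxia with glycolysis, interferon-stimulated genes and clock genes. Luminal, basal with stromal, and leukocyte with endothelial markers complete them. Of 430 genes listed, 391 were measured, and 2 genes stood in more than 1 list. The overlap of the E2 comparisons was set against 50 simulations in which no gene changed and both E2 groups shared 1 simulated control group. Control probe sets were compared by an exact permutation test over all 280 partitions of the arrays into groups of 3. Its statistic was the variance of the 3 group means, so it tests any difference among the groups.

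Named genes followed a rule: for each E2 time against vehicle, the 6 largest rises and 6 largest falls among called genes whose arrays did not overlap between groups and whose higher group mean exceeded the median of all genes (7.97), the 2 called members of each list with the largest change, and always ESR1, PGR, GREB1 and TFF1. For E2 6 h against E2 3 h the 4 largest rises and 4 largest falls were taken. Genes outside the rule that are named as examples of a list were chosen after their values were seen. Groups, tests, lists, this rule and most alternatives were set before the data were examined.

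The fit was tested on simulated data for the comparison of E2 6 h with vehicle over 19775 genes. It recovered 83% of 100 genes changed by 0.5 log2 and 98% of 100 genes changed by 1.0 log2, and called 9 of 19575 unchanged genes. Camera called a simulated list of 25 genes shifted by 0.2 log2, and 6 of 100 unshifted lists passed an unadjusted threshold of 0.05. The simulated genes were independent of each other, while the estimated correlation within a real list reached 0.570. The simulation therefore does not give camera's rate of false calls for the real lists.

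The alternatives were median centring, quantile normalization, genes above the median expression alone, the mean of all probe sets of a gene, leaving out probe sets prone to cross-hybridisation (x_at and s_at), every probe set on its own, a fit of the compared groups alone, an intensity trend with robust settings, array weights, the replicate number as a block, each array left out in turn, and an adjusted p under 0.01. Cyclic loess normalization and a fit without both the E2 3 h arrays and vehicle replicate 2 were added after seeing the data.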

Results

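The series measured how the transcriptome of MCF-7 breast cancer cells differed after E2, the main estrogen, at early times. MCF-7 cells depend on estrogen for growth and carry estrogen receptor alpha. RMA log2 values of 19775 genes were compared between vehicle at 3 h, E2 at 3 h and E2 at 6 h, with 3 arrays per group. The labels describe the arrays as biological replicates and do not say whether they came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

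The E2 3 h arrays stood apart from the other 6 in technical measures as well. They correlated with the other arrays at r = 0.987 to 0.993 across probe sets, while the vehicle and E2 6 h arrays correlated with each other at 0.995 to 0.998. The control probe set for the 5′ part of 28S ribosomal RNA read 10.4 ± 0.112 (SD, n = 3) on the E2 3 h arrays, 7.54 ± 0.290 with vehicle and 7.87 ± 0.352 with E2 for 6 h (exact permutation p = 0.0107, adjusted p = 0.0429 over 6 control measures). The permutation p-values here test any difference among the 3 groups, not E2 3 h against vehicle alone. The 5′ part of 18S ribosomal RNA read 7.06 ± 1.76 on the E2 3 h arrays, 4.97 ± 0.136 with vehicle and 5.10 ± 0.145 with E2 for 6 h (SD, n = 3, exact permutation p = 0.0143 over the 3 groups, adjusted p = 0.0429). Its difference between E2 3 h and vehicle was 2.09 log2, and 1.08 without E2 3 h replicate 2. The hybridisation controls read 11.2 ± 0.062 on the E2 3 h arrays, 10.3 ± 0.550 with vehicle and 10.0 ± 0.204 with E2 for 6 h (SD, n = 3, exact permutation p = 0.0214 over the 3 groups, adjusted p = 0.0429). They were higher with E2 for 3 h than with vehicle by 0.90 log2. The difference between 3′ and 5′ signal did not differ detectably for GAPDH, ACTB or STAT1 (exact permutation p = 0.664, 1 and 0.929). Fold changes at 3 h also followed brightness: in the brightest of 10 bins of genes the median was 0.35 log2 for E2 3 h against vehicle and 0.03 for E2 6 h against vehicle. The E2 3 h samples carry titles of another style than the other 6: theirs begin with "New", and those of the other 6 do not. The titles do not say in what sense these samples were new. Since each group lay on 1 side of this division, batch and group cannot be told apart for the comparisons that use E2 3 h.

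**Figure D1:**
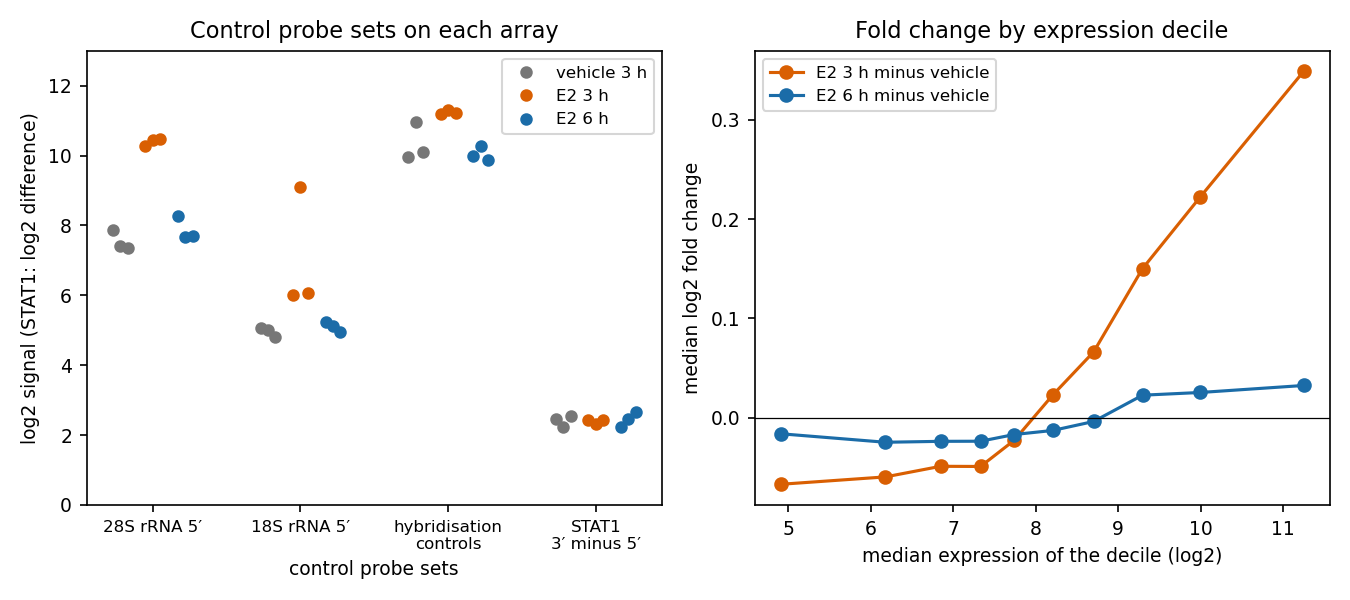
Control probe sets on each array (left, log2 signal, with STAT1 as the log2 difference of its 3′ and 5′ probe sets) and the median log2 fold change of genes in 10 bins of mean expression (right). Each point at left is an array. The 28S signal averaged 10.4 on the E2 3 h arrays and 7.54 on the vehicle arrays, and the brightest bin had a median change of 0.35 log2 at 3 h against 0.03 at 6 h.

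After 3 h of E2, estrogen-induced genes were higher almost without exception. Of the 35 measured members of that list, 34 rose and 0 fell, with a median of 0.84 log2. EGR3, an early-response zinc finger transcription factor, rose 5.02-fold, from 8.31 ± 0.13 to 10.64 ± 0.08 log2 (SD, n = 3, log2 change 2.33 ± 0.08 SE, limma adjusted p = 3.5e-10). MYBL1, a MYB family transcription factor, rose by 1.71 ± 0.07 log2 (SE, adjusted p = 5.0e-09), although another of its probe sets fell by 0.48. PGR, the progesterone receptor, rose 2.33-fold (1.22 ± 0.08 log2, adjusted p = 2.6e-07) and GREB1, an estrogen receptor cofactor, 1.53-fold (0.61 ± 0.07 log2, adjusted p = 4.2e-05). MYC and CCND1, drivers of cell cycle entry named after their values were seen, rose by 1.56 and 0.70 log2 (0.34 for CCND1 under quantile normalization). TFF1, a secreted trefoil peptide already near the top of the scale at 14.2 ± 0.171, rose by 0.28 log2 (adjusted p = 0.019), a call that ended under quantile normalization, turned to a fall of -0.24 under cyclic loess and was lost without vehicle replicate 2 or 3 or E2 3 h replicate 2 (0.28, 0.19 and 0.25). ESR1, the receptor's own gene, had a change of 0.18 log2 (adjusted p = 0.088), called at 0.25 without vehicle replicate 1, not called at 0.11 without vehicle replicate 3, and called as a fall under quantile normalization (-0.26) and cyclic loess (-0.22). The rise of GREB1 was 0.21 and 0.25 under those scalings. The shift of the estrogen-induced list had a camera adjusted p of 1.7e-20 (adjusted p = 0.331 with an estimated correlation). Of the 18 lists, camera called 12 at 3 h, 10 up and 2 down, and with an estimated correlation 0, with 1 at an unadjusted p under 0.05 and 15 by fry.

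Estrogen-repressed genes went both ways at 3 h: 9 of 24 fell, 3 rose, and the median was -0.09 log2 (camera adjusted p = 0.013, adjusted p = 0.405 with an estimated correlation). CYP1A1, a xenobiotic-metabolising enzyme, fell by 0.81 ± 0.13 log2 (SE, adjusted p = 0.00031), while BCL6, a transcriptional repressor, rose by 0.82 ± 0.09 log2 (adjusted p = 2.3e-05, 0.42 with the mean of all probe sets). Of 23 immediate early genes 15 rose and 1 fell, including EGR1 at 1.64 log2 and FOS at 1.44 log2 (camera adjusted p = 0.00041, adjusted p = 0.405 with an estimated correlation). Ribosome biogenesis genes rose in 19 of 23 cases, with a median of 0.40 log2 (camera adjusted p = 1.3e-06, adjusted p = 0.331 with an estimated correlation). RCL1 rose by 1.01 log2 and WDR43 by 0.94 log2, and RCL1 had a change of -0.02 when s_at and x_at probe sets were left out. These 4 lists also passed camera under quantile normalization and cyclic loess, with other medians: 0.46 and 0.49 for estrogen-induced, -0.23 and -0.22 for estrogen-repressed, 0.08 and 0.09 for immediate early (0.27 as deposited) and 0.17 and 0.19 for ribosome biogenesis genes. Among 10000 random lists matched on expression the immediate early median as deposited lay at percentile 84.5 (random median 0.21). The estrogen-induced, estrogen-repressed and ribosome biogenesis medians lay at percentiles 100, 0.01 and 100.

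The other 8 lists called at 3 h lost their call under both quantile normalization and cyclic loess. Of 31 G1/S and replication genes 18 rose and 1 fell, led by RRM1 (0.61 log2) and MCM7 (0.55 log2). Of 27 mitosis genes 13 rose and 0 fell, led by TOP2A (1.04 log2, 0.32 without x_at and s_at probe sets) and BIRC5 (0.75 log2), the latter not called under quantile normalization (0.37). In the unfolded protein response and amino acid list 14 of 25 rose and 1 fell, the median of 0.27 turning to -0.01 under quantile normalization, with CEBPB at 0.86 log2 and SLC7A5 at 0.69 log2. Heat shock genes rose in 10 of 13 cases and fell in 1, with STIP1 at 0.52 log2 and DNAJA1 at 0.51 log2. Hypoxia and glycolysis genes rose in 14 of 21 cases and fell in 2, with MXI1 at 0.49 log2 and GPI at 0.47 log2. Interferon-stimulated genes rose in 14 of 21 cases and fell in 1, the median of 0.27 turning to -0.03 under both scalings, with IFI6 at 0.72 log2 and BST2 at 0.63 log2. Luminal epithelial markers rose in 10 of 16 cases, with FOXA1 at 0.64 log2 and AGR2 at 0.51 log2, and their list median of 0.27 turned to -0.02 under quantile normalization and -0.06 under cyclic loess. Leukocyte and endothelial markers fell in 4 of 14 cases, with MS4A1 at -0.44 log2 (-0.27 without x_at and s_at probe sets) and CD2 at -0.38 log2, and this list was not called without E2 3 h replicate 2 (-0.08). MS4A1 read 6.55 to 7.19 log2 over the arrays, below the median of all genes (7.97), and CD2 7.80 to 8.39. Without detection calls these signals could not be told from background. Among genes above the median expression the leukocyte and endothelial list alone of these 8 stayed called, the other medians being 0.24 to 0.42. Without x_at and s_at probe sets the unfolded protein response, hypoxia, interferon and leukocyte lists were not called (0.13, 0.19, 0.25 and -0.08). Camera adjusted p for these 8 lists lay between 0.00073 and 0.022, and between 0.331 and 0.514 with an estimated correlation. Among 10000 random lists matched on expression their medians lay at percentiles 77.8, 44.1, 77.6, 96.8, 97.4, 65.4, 10.5 and 10.5, in the order given above. A general shift by brightness was thus not told apart from a shift of these lists. The calls of MXI1, GPI, DNAJA1, FOXA1, AGR2 and IFI6 ended under both scalings, and that of IFI6 also without vehicle replicate 3 (0.49) or E2 3 h replicate 3 (0.48). RRM1, MCM7, CEBPB, SLC7A5, STIP1 and BST2 stayed called under quantile normalization at 0.30, 0.20, 0.42, 0.25, 0.26 and 0.34 log2.

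The remaining 6 lists did not pass camera at 3 h. Under quantile normalization the medians above 0 among them, those of the antiproliferative, growth factor, nuclear receptor and sterol lists, turned to -0.09, -0.11, -0.17 and -0.09. The rises of IGF1R, NSDHL and NFIL3 given next were 0.72, 0.33 and 0.16 log2 under quantile normalization. Antiproliferative and cell death genes included 12 rises and 3 falls among 23 (adjusted p = 0.138, called without vehicle replicate 1 at a median of 0.26), with the death gene PMAIP1 up by 1.45 log2 and the cyclin-dependent kinase inhibitor CDKN2B down by -1.06 log2 (-0.45 with the mean of all probe sets). Growth factors and receptors included 7 rises and 6 falls among 27 (adjusted p = 0.982), with IGF1R at 1.09 log2 and EGFR at -1.62 log2 (0.46 and -0.38 with the mean of all probe sets). Nuclear receptors and coregulators had 4 rises and 3 falls among 19 (adjusted p = 0.763), with NR1D2 at 0.69 log2, not called under either scaling, and NCOA7 at -0.63 log2 (0.36 and -0.17 with the mean of all probe sets). For growth factors and nuclear receptors the median and mean were above 0 while the test's direction was down. Sterol and fatty acid synthesis genes had 10 rises and 3 falls among 19 (adjusted p = 0.052, called without vehicle replicate 1 or 2, E2 3 h replicate 2 or E2 6 h replicate 1 or 2, at medians of 0.29, 0.30, 0.28, 0.26 and 0.26), with NSDHL at 0.53 log2 and DHCR7 at 0.52 log2, the latter not called under quantile normalization (0.17). Clock genes had 1 rise and 2 falls among 15 (adjusted p = 0.182), namely NFIL3 at 0.28 log2, and BHLHE41 at -0.25 log2, whose change was 0.09 without x_at and s_at probe sets. The other fall was BHLHE40 (-0.23 log2), named after its value was seen. The BHLHE41 call was also lost in a fit of the compared groups alone (-0.25) and without vehicle replicate 2 or 3 or E2 3 h replicate 2 or 3 (-0.25, -0.18, -0.18 and -0.24). Basal and stromal markers had 1 rise and 4 falls among 17 (adjusted p = 0.057, called without vehicle replicate 1 at a median of -0.10), with ZEB1 at -0.31 log2 and COL1A2 at -0.30 log2.

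Among the largest single changes at 3 h were rises of KCNK6, a potassium channel (3.55-fold, 1.83 ± 0.09 log2, SE), H3-3A, a histone gene (1.70 ± 0.32 log2), USP31 (1.69 ± 0.12 log2) and FOXN1, a forkhead transcription factor (1.68 ± 0.08 log2). The largest falls were CARD16 (-2.03 ± 0.17 log2), TCP11L2 (-1.69 ± 0.10), EGFR, the epidermal growth factor receptor (-1.62 ± 0.15), DYNLT2 (-1.22 ± 0.13), LRRC25 (-1.19 ± 0.12) and ST8SIA4, a polysialyltransferase (-1.10 ± 0.10). Several of these were smaller over more probe sets: with the mean of all probe sets of a gene the change was -0.26 for TCP11L2, -0.38 for EGFR, -0.36 for DYNLT2, -1.13 for CARD16, -0.69 for ST8SIA4, 1.01 for USP31 and 0.43 for MYBL1. Other genes named at 3 h were also smaller that way: 1.07 for EGR1, 0.47 for TOP2A, 0.45 for BIRC5, 0.58 for RCL1, 0.29 for AGR2, -0.15 for ZEB1 and -0.08, not called, for BHLHE41. One EGFR probe set rose by 0.34. Of the 48 genes named at 3 h, 33 had several probe sets, 3 of them (EGFR, IGF1R and MYBL1) with another called in the opposite direction, and 8 called genes (AGR2, BHLHE41, CDKN2B, DYNLT2, MYBL1, NCOA7, NR1D2 and ZEB1) were called by 1 probe set alone.

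In all, 8057 of 19775 genes were called at 3 h, 5239 higher and 2818 lower (65.0% higher). This split depended on scaling: quantile normalization gave 2364 higher and 3512 lower (40.2% higher) and cyclic loess 2598 higher and 3330 lower (43.8% higher). It depended on brightness too: as deposited, 71.1% of the genes called lower at 3 h lay below the median expression, against 16.7% of those called higher. Of the genes called lower at 6 h 27.1% did. Among genes above the median expression alone, 4542 were higher and 859 lower at 3 h. Changes above 1 log2 were seen in 77 genes upward and 14 downward. Arrays did not overlap between the groups for 47.3% of genes, where chance gives 10%.

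**Figure D2:**
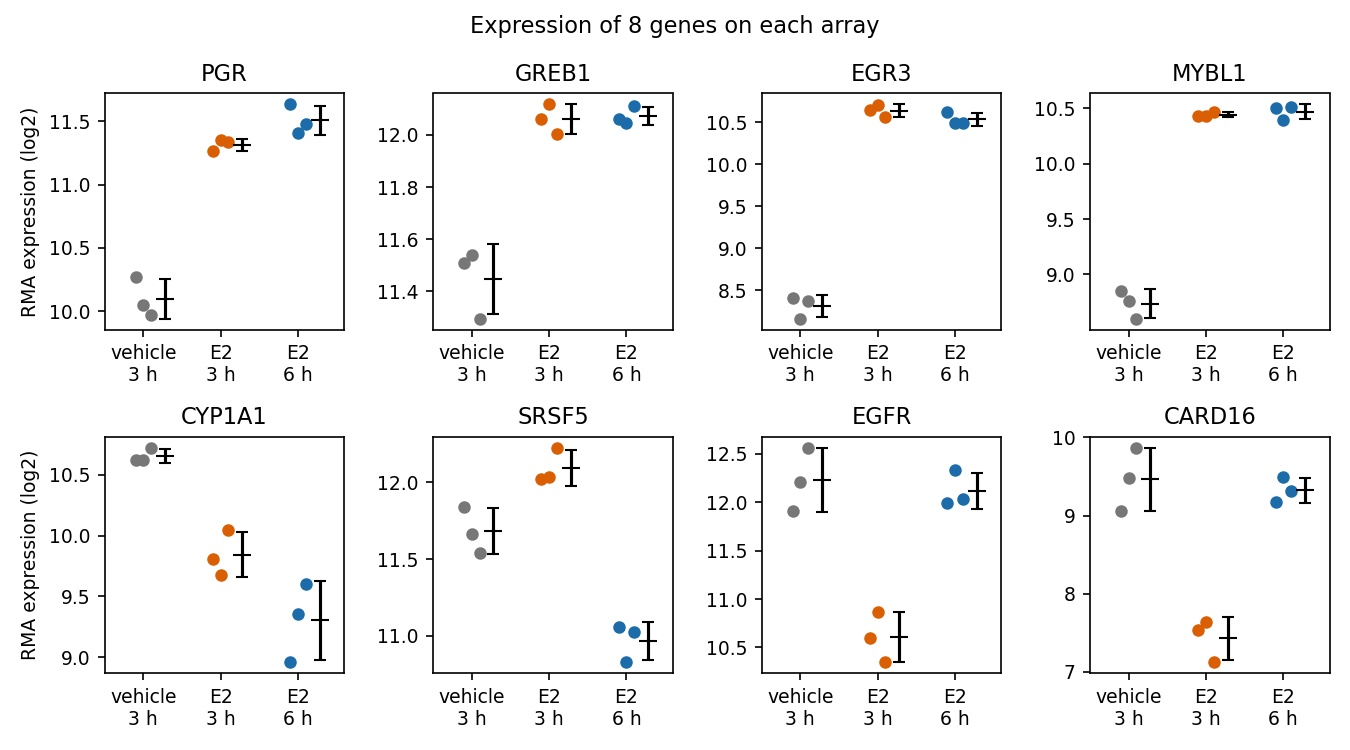
RMA expression (log2) of 8 genes on each array, with group means and SD (black, n = 3). The y axes differ between panels and do not start at 0. PGR, GREB1, EGR3 and MYBL1 were higher at both E2 times, CYP1A1 fell by 0.81 and 1.35 log2, SRSF5 changed by 0.41 (-0.003 under quantile normalization, not called) and -0.71 log2, and EGFR and CARD16 were lower at 3 h alone by the probe sets shown.

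After 6 h of E2, the estrogen-induced genes were again higher than with 3 h vehicle: 27 of 35 rose and 0 fell, with a median of 0.59 log2 (camera adjusted p = 3.4e-58, and adjusted p = 0.0498 with an estimated correlation, the only list of 18 that passed that way, with 3 at an unadjusted p under 0.05 and 3 by fry). EGR3 rose 4.66-fold (2.22 ± 0.08 log2, SE, adjusted p = 6.9e-10), MYBL1 3.33-fold (1.73 ± 0.07 log2, by 1 probe set alone) and PGR 2.66-fold (1.41 ± 0.08 log2, adjusted p = 1.5e-07). GEM, a small GTP-binding protein, rose by 1.58 ± 0.06 log2 and IGFBP4, which binds insulin-like growth factors, by 1.45 ± 0.12 log2. LINC01588, a long noncoding RNA, rose by 1.58 ± 0.11 log2, a call lost without x_at and s_at probe sets (0.12). That setting took the brightest remaining probe set, at a mean of 7.33 log2. Another one at 7.28, also neither x_at nor s_at, rose by 0.91 log2 (limma adjusted p = 0.00061 with every probe set tested). GREB1 rose by 0.62 ± 0.07 log2 (adjusted p = 9.5e-05). TFF1 and ESR1 had changes of 0.15 and -0.20 log2 that did not pass (adjusted p = 0.59 and 0.31), and ESR1 passed as a fall under quantile normalization, cyclic loess and array weights (-0.26, -0.25 and -0.20). The ESR1 value was -0.12 without vehicle replicate 1, and the TFF1 value 0.23 without vehicle replicate 1, 0.06 without vehicle replicate 3 and 0.08 without E2 6 h replicate 1.

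The largest falls at 6 h were CYP1A1 (-1.35 ± 0.13 log2, SE, adjusted p = 1.1e-05), RASL11B, a small GTPase-like gene (-0.94 ± 0.09), ST8SIA4 (-0.76 ± 0.10), TNFSF10, the death ligand TRAIL (-0.72 ± 0.11), SRSF5, a splicing factor (-0.71 ± 0.09), and TRERF1 (-0.69 ± 0.07). Estrogen-repressed genes fell in 5 of 24 cases and rose in 1, with a median of -0.23 log2 (camera adjusted p = 8.3e-09, adjusted p = 0.069 with an estimated correlation), CYP1A1 and BMF, a cell death gene (-0.46 log2), leading the falls. Of 23 immediate early genes 5 rose, among them KLF4 by 0.68 log2 (camera adjusted p = 1.2e-07, adjusted p = 0.287 with an estimated correlation). Ribosome biogenesis genes rose in 4 of 23 cases, with NOC3L at 0.49 log2 and RCL1 at 0.41 log2, the latter -0.02 without x_at and s_at probe sets (camera adjusted p = 0.00012, adjusted p = 0.445 with an estimated correlation). Small shifts were also called for mitosis genes (median 0.10 log2, 1 of 27 called, camera adjusted p = 0.00011) and G1/S genes (median 0.07 log2, 0 of 31 called, camera adjusted p = 0.0074), with adjusted p of 0.717 and 0.835 given an estimated correlation. The G1/S shift was not called under quantile normalization, among genes above the median expression, without x_at and s_at probe sets or without vehicle replicate 3 (0.02, 0.07, 0.02 and 0.04). The mitosis gene called was TOP2A (0.59 log2), whose call ended at about the same size under quantile normalization and cyclic loess (0.56 in each), with an intensity trend and robust settings and with every probe set tested (0.59 in each). It also ended without vehicle replicate 2 or 3, E2 3 h replicate 1 or E2 6 h replicate 1 or 2 (0.45, 0.66, 0.59, 0.47 and 0.62).

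Nuclear receptors and interferon-stimulated genes shifted downward at 6 h by little. The nuclear receptor list had a median of -0.09 log2, with VDR, the vitamin D receptor, down by -0.45 log2 as 1 called gene of 19 (camera adjusted p = 0.025, adjusted p = 0.445 with an estimated correlation). It was not called with the mean of all probe sets (-0.08), without x_at and s_at probe sets (-0.06), or without vehicle replicate 1 (-0.08) or E2 6 h replicate 1 (-0.09). The interferon list had a median of -0.07 log2, with OAS1 (-0.34 log2) and OAS2 (-0.30 log2), sensors of double-stranded RNA, as the 2 called genes of 21 (camera adjusted p = 0.026, adjusted p = 0.835 with an estimated correlation). It was not called without vehicle replicate 1 or 2 or E2 6 h replicate 2 or 3 (-0.04, -0.04, -0.01 and -0.08). The OAS2 call was lost with the mean of all probe sets (-0.23, adjusted p = 0.105), with every probe set tested (-0.30, adjusted p = 0.059) and without vehicle replicate 2 or 3 or any 1 of the E2 6 h replicates (-0.23, -0.34, -0.32, -0.28 and -0.31).

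In the 10 lists not called by camera at 6 h, few genes were called. Among 10000 random lists matched on expression, the sterol, growth factor, luminal and antiproliferative medians lay at percentiles 0.20, 0.76, 1.79 and 99.5. The others of these lists lay between percentiles 3.46 and 79.5. Random lists lack the correlation within real ones, so such percentiles are weak evidence of a shift. Antiproliferative genes had 2 rises and 3 falls among 23 (camera adjusted p = 0.159, called without vehicle replicate 1 at a median of 0.19), with CDKN2B at -0.81 log2 and PMAIP1 at 0.78 log2. Growth factors had 3 rises, led by TGFA (0.74 log2) and VEGFA (0.67 log2), and 2 falls among 27 (adjusted p = 0.858). In the unfolded protein response list 3 of 25 rose (adjusted p = 0.159, called without vehicle replicate 1 at a median of 0.04), with CEBPB at 0.57 log2 and SLC7A5 at 0.46 log2, the latter not called without vehicle replicate 2 or 3 or E2 6 h replicate 1 or 3 (0.50, 0.36, 0.41 and 0.45). Hypoxia genes had 3 rises and 1 fall among 21 (adjusted p = 0.974), with MXI1 at 0.57 log2, not called without vehicle replicate 2 or E2 6 h replicate 1 (0.44 and 0.50), and DDIT4 at -0.54 log2. Heat shock had 1 rise among 13 (adjusted p = 0.454), CHORDC1 at 0.45 log2, and luminal markers 1 fall among 16 (adjusted p = 0.415, called without vehicle replicate 3 at a median of -0.10), ELF3 at -0.45 log2. Both calls were lost without x_at and s_at probe sets (0.07 and -0.21). No called gene was found among 19 sterol (adjusted p = 0.457, called without vehicle replicate 3 at a median of -0.11), 15 clock (adjusted p = 0.858), 17 basal and stromal (adjusted p = 0.457) or 14 leukocyte and endothelial genes (adjusted p = 0.868). Median and mean differed in sign for growth factors (-0.05 and 0.01), hypoxia (-0.02 and 0.02) and clock genes (-0.04 and 0.01).

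With the mean of all probe sets of a gene the change was 0.57 for MYBL1, 0.25 for TGFA, 0.31 for VEGFA, -0.47 for RASL11B, -0.37 for TRERF1, 0.87 for LINC01588, 0.36 for TOP2A, 0.25 for RCL1, -0.49 for CDKN2B, -0.27 for VDR, 0.26 for CHORDC1, -0.29 for ELF3 and -0.12 for ESR1.

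In all, 690 genes were called at 6 h, 550 higher and 140 lower (79.7% higher), with 586 higher and 278 lower (67.8% higher) under quantile normalization and 574 higher and 214 lower (72.8% higher) under cyclic loess. Changes above 1 log2 were seen in 27 genes upward and 2 downward. Arrays did not overlap between the groups for 17.7% of genes, where chance gives 10%. Treatment and time in culture differ together here, because no 6 h vehicle was analysed. Fitted without the E2 3 h arrays, the comparison called 819 genes, and without vehicle replicate 2 as well 307. The count was 395 without vehicle replicate 2, 434 without vehicle replicate 3, and 430, 445 and 441 without E2 6 h replicates 1, 2 and 3. It was 2294 with array weights. Of the 33 genes named at 6 h, 22 had several probe sets, and with every probe set tested 9 called genes (CDKN2B, CHORDC1, ELF3, MYBL1, RASL11B, TGFA, TOP2A, TRERF1 and VEGFA) had 1 probe set called and 1 (OAS2) had none. For TOP2A it was not the probe set reported but another, at 0.41 log2.

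**Figure D3:**
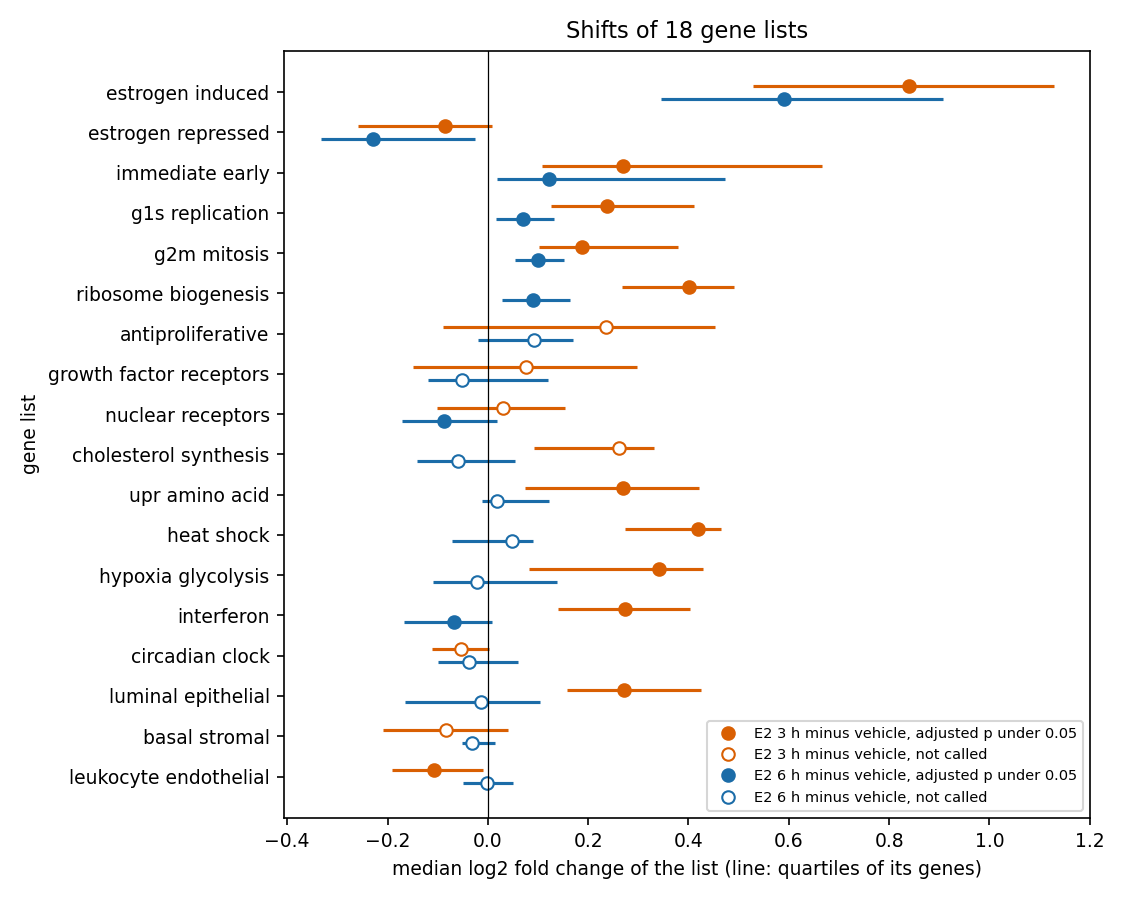
Median log2 fold change of each of the 18 gene lists (x axis) for E2 3 h and E2 6 h against vehicle, with lines between the quartiles of its genes and filled points where camera's adjusted p was under 0.05. Estrogen-induced genes had medians of 0.84 and 0.59 log2, and of 0.46 and 0.55 under quantile normalization, where the order of the times turned. The luminal median at 3 h, 0.27, turned to -0.02 under quantile normalization, and the interferon median, also 0.27, to -0.03.

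Adjusted over the list alone, the calls changed little at 3 h: rises numbered 34 for estrogen-induced, 16 for immediate early, 21 for G1/S, 13 for mitosis, 20 for ribosome biogenesis, 15 for unfolded protein response, 15 for interferon and 12 for luminal genes, and falls 9 for estrogen-repressed and 3 for basal and stromal genes, and nuclear receptors had 3 rises. The other lists' counts were those over all genes tested. At 6 h, adjusted over the list alone, 30 estrogen-induced genes rose and 13 estrogen-repressed genes fell, against 27 and 5 when adjusted over all genes tested. Adjusted over the list alone there were also 6 immediate early, 5 ribosome biogenesis, 5 antiproliferative, 4 growth factor, 4 unfolded protein response, 2 heat shock, 1 interferon and 1 clock gene higher, and 5 growth factor, 3 hypoxia, 2 nuclear receptor, 2 luminal, 1 heat shock and 1 unfolded protein response gene lower.

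Genes called at both times mostly moved the same way. Of 481 such genes, 458 had the same direction, 395 up and 63 down, and 23 had opposite directions. Simulated unchanged groups against a common simulated vehicle group shared 0.02 genes on average and at most 1 over 50 draws. With no gene changed almost none is called, so this does not measure the sharing that a common control gives to 2 changed groups. Independent lists of the real sizes would share 146 upward and 19.95 downward. The vehicle group has too few arrays to be split, so part of the excess may come from the shared controls. Across all genes the covariance of the changes was 0.0159 against 0.00366 in simulation, and the correlation across genes was 0.427, below that in simulation, genes not being independent replicates. Of the 458 genes, 120 changed more at 3 h, 50 changed more at 6 h and 288 were not called between the times. The shared count was 284 without vehicle replicate 2, 296 without vehicle replicate 3 and 301 without E2 6 h replicate 1. Among the opposite genes, SRSF5 changed by 0.41 and -0.71 log2, VDR by 0.30 and -0.45, OAS1 by 0.34 and -0.34, and CHORDC1 by -0.26 and 0.45. The 3 h changes of SRSF5, VDR and OAS1 were not called under quantile normalization (-0.003, 0.14 and 0.03) or cyclic loess (0.07, 0.18 and 0.07), while CHORDC1 stayed called at both times. Quantile normalization gave 39 opposite genes and cyclic loess 42, of which 12 and 13 were among the 23.

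**Figure D4:**
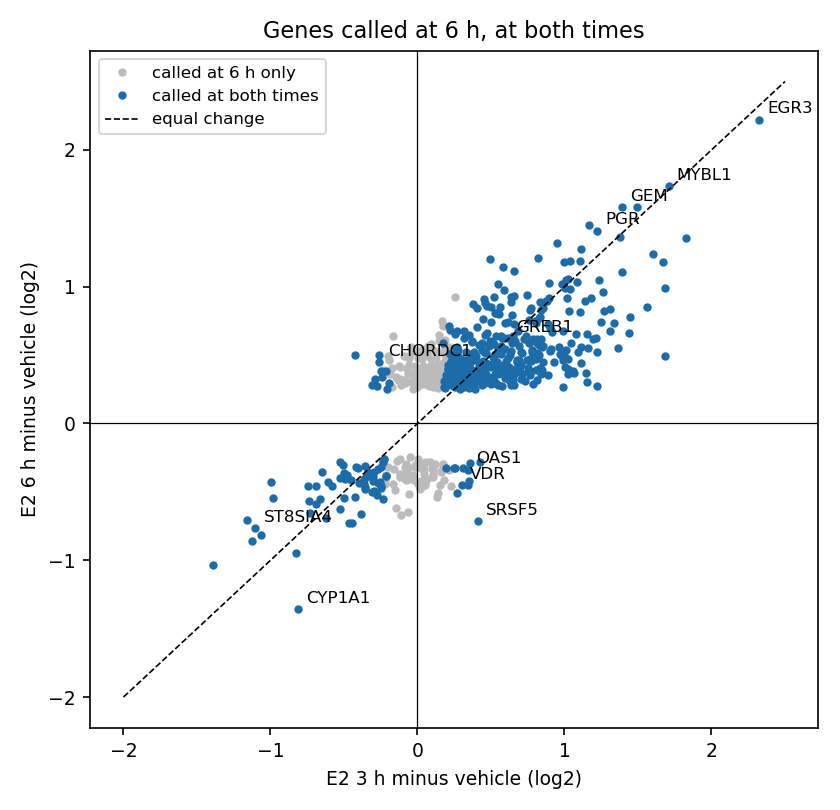
Log2 changes against vehicle at 3 h (x axis) and 6 h (y axis) of the 690 genes called at 6 h, each point a gene. Of these, 597 (86.5%) had the same sign at both times; SRSF5, VDR and OAS1, whose 3 h changes were not called under quantile normalization or cyclic loess, lie at lower right and CHORDC1 at upper left.

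Between the E2 times, the 8 genes named for the largest differences were each called at 3 h and not at 6 h. Higher at 6 h than at 3 h were CARD16 (1.89 ± 0.17 log2, SE), TCP11L2 (1.53 ± 0.10), EGFR (1.52 ± 0.15) and LRRC25 (1.16 ± 0.12). Lower at 6 h were H3-3A (-1.46 ± 0.32), CBX5, a heterochromatin protein (-1.36 ± 0.29), P2RY2, a nucleotide receptor (-1.32 ± 0.07), and CDC42SE1 (-1.19 ± 0.15). H3-3A changed by -0.95 without E2 3 h replicate 2, and with the mean of all probe sets EGFR changed by 0.32, TCP11L2 by 0.20, CARD16 by 1.07, CBX5 by -0.65 and CDC42SE1 by -0.76. CDC42SE1 changed by -0.34 without x_at and s_at probe sets. PGR, GREB1 and EGR3 were not called between the times, with changes of 0.19, 0.01 and -0.11 log2.

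Among the lists, 7 were lower at 6 h than at 3 h and 1 higher. Ribosome biogenesis had a median of -0.29 log2, interferon -0.35, luminal -0.32, heat shock -0.39, G1/S -0.21, sterol -0.25 and hypoxia -0.17, and leukocyte and endothelial genes 0.07. Camera adjusted p lay between 0.00061 and 0.042 for these lists, and adjusted p was 0.658 for each of them with an estimated correlation. Under quantile normalization and under cyclic loess none of the 18 lists was called by camera (0, with 3 at an unadjusted p under 0.05 in each, and 7 and 6 by fry), and the sterol median turned to 0.03 and 0.01 and the G1/S median to 0.02 and -0.02. The call of 8 lists became 5 without E2 3 h replicate 2 and 5 without E2 3 h replicate 3. The hypoxia call was lost without E2 3 h replicate 2 or 3 or E2 6 h replicate 2 at medians no smaller than before (-0.20, -0.20 and -0.18), and the G1/S call without E2 3 h replicate 2 at -0.20. The leukocyte call was lost without the same 3 arrays, at medians of 0.035, 0.10 and 0.08, and the sterol call without E2 3 h replicate 3 (median -0.22). The estrogen-induced list was not called between the times (median -0.13 log2, 0.13 under quantile normalization, camera adjusted p = 0.088), but was called without E2 6 h replicate 1 (-0.19). For the other 9 lists adjusted p lay between 0.068 and 0.889. Among them the immediate early list was called without E2 6 h replicate 3 (-0.20), the mitosis list without E2 3 h replicate 1 or E2 6 h replicate 1 (-0.14 and -0.16), and the unfolded protein response list without vehicle replicate 3 or E2 6 h replicate 1 (-0.21 in each).

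In all, 7311 genes were called between the E2 times, 2516 higher and 4795 lower at 6 h (34.4% higher). Of the genes higher at 6 h 64.9% lay below the median expression, against 19.8% of those lower. Adjusted over the list alone, 18 G1/S, 11 sterol, 11 heat shock and 14 luminal genes were lower at 6 h, against 15, 10, 10 and 11 over all genes tested. Quantile normalization gave 3368 higher and 2607 lower (56.4% higher) and cyclic loess 3414 higher and 2793 lower (55.0% higher). The count was 4831 without E2 6 h replicate 2.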

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

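The tests of why many more genes were called at 3 h, and of the largest falls at 3 h, were chosen only after those results were seen, as were the other settings for the genes and control probe sets listed here and the percentiles of each E2 time against vehicle; the tests of the interferon and luminal lists and of other splits of the arrays were set before.

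Of 66 named genes, 47 differed between the E2 times by limma, 34 lower and 13 higher at 6 h, which is a test of the difference itself. Of all genes tested 37.0% were called between the times, 34.4% of these higher at 6 h. The count of named genes is favoured by their choice, since many were named for large changes on the same E2 3 h arrays. Among genes named for large changes or for estrogen response, the log2 changes from 3 h to 6 h were -0.47 for KCNK6, -1.46 for H3-3A, -1.19 for USP31, -0.69 for FOXN1, 1.89 for CARD16, 1.53 for TCP11L2, 1.52 for EGFR, 1.13 for DYNLT2, 1.16 for LRRC25, 0.34 for ST8SIA4, -0.73 for BCL6, -0.54 for CYP1A1, -0.38 for ESR1, 0.19 for GEM, -1.12 for SRSF5 and -0.21 for BMF. Immediate early, cell cycle, ribosome and cell death genes gave -0.99 for EGR1, -0.32 for KLF4, -0.59 for RRM1, -0.39 for MCM7, -0.45 for TOP2A, -0.60 for BIRC5, -0.60 for RCL1, -0.98 for WDR43 and -0.67 for PMAIP1. Receptors and coregulators gave -0.73 for IGF1R, 0.26 for NCOA7 and -0.75 for VDR. Metabolic and stress genes gave -0.43 for NSDHL, -0.30 for DHCR7, -0.29 for CEBPB, -0.80 for STIP1, -0.44 for DNAJA1, 0.71 for CHORDC1 and -0.55 for GPI. Interferon and clock genes gave -0.84 for IFI6, -0.68 for BST2, -0.68 for OAS1, -0.34 for OAS2 and -0.27 for NFIL3. Cell type markers gave -0.39 for FOXA1, -0.37 for AGR2, -0.60 for ELF3, 0.25 for ZEB1, 0.30 for COL1A2, 0.47 for MS4A1 and 0.34 for CD2.

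Many of these differences depended on scaling. Under quantile normalization 31 of the 47 stayed called in the same direction and 16 were not called, and under cyclic loess 33 and 14. Not called under either were CYP1A1, EGR1, MCM7, TOP2A, BIRC5, IGF1R, DHCR7, CEBPB, DNAJA1, FOXA1, AGR2, ESR1, BMF and KLF4, and under quantile normalization also GPI and IFI6. ESR1 was -0.004 under quantile normalization and -0.022 under cyclic loess. Without E2 6 h replicate 3 IGF1R was -0.48, and without E2 3 h replicate 2 H3-3A was -0.95. Calls were also lost for NCOA7 without vehicle replicate 3 (0.26), and without E2 3 h replicate 1 for ST8SIA4 (0.22), EGR1 (-0.83), TOP2A (-0.45), NCOA7 (0.19) and FOXA1 (-0.30). Without E2 3 h replicate 2 they were lost for TOP2A (-0.30), FOXA1 (-0.34) and KLF4 (-0.22), and without E2 3 h replicate 3 for NCOA7 (0.27), DHCR7 (-0.24), GEM (0.18), BMF (-0.14) and KLF4 (-0.30). Leaving out E2 6 h replicate 1 ended those of FOXA1 (-0.41), GEM (0.19) and KLF4 (-0.30). Leaving out E2 6 h replicate 2 ended those of EGR1 (-0.77), TOP2A (-0.42), NCOA7 (0.29), DHCR7 (-0.23), GEM (0.21), BMF (-0.21) and KLF4 (-0.30). Leaving out E2 6 h replicate 3 ended those of ST8SIA4 (0.27), TOP2A (-0.36), NCOA7 (0.18), FOXA1 (-0.29), GEM (0.16) and BMF (-0.18).

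The lists that differed between the E2 times had medians of -0.21 for G1/S, -0.29 for ribosome biogenesis, -0.25 for sterol synthesis, -0.39 for heat shock, -0.17 for hypoxia, -0.35 for interferon, -0.32 for luminal and 0.073 for leukocyte and endothelial genes. For each of them adjusted p = 0.658 with an estimated correlation, none was called under quantile normalization or cyclic loess, and the sterol median turned to 0.03 under quantile normalization. Control probe sets, which the gene comparisons do not use, were higher on the E2 3 h arrays than with vehicle by 2.87 log2 for 28S, 2.09 for 18S (1.08 without E2 3 h replicate 2) and 0.90 for the hybridisation controls. Outlying arrays within a group were not tested, since each group held 3.

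Many more genes were called at 3 h (8057) than at 6 h (690). Cyclic loess left 5928 genes at 3 h against 788 at 6 h, which argues against intensity-dependent scaling as the whole cause. The STAT1 control's 3′ minus 5′ signal differed from vehicle by -0.016 log2, which argues against degraded RNA. In genes called at 3 h alone a second probe set kept a median of 0.503 of the first one's change (0.407 to 0.628, 95% bootstrap interval). In matched genes called at 6 h it kept 0.832 (0.763 to 0.902), 254 genes in each. The first probe set was the brighter one by choice, and its brightness was not matched. Changes rose with brightness at 3 h (medians of 0.02 in bin 6 and 0.35 in bin 10) more than at 6 h (-0.01 and 0.03). A dimmer second probe set would keep less at 3 h by that trend alone. The shares therefore cannot tell signal specific to single probe sets from the trend, and either may contribute. The hybridisation controls, which do not measure genes of the cells, read 11.2 ± 0.062 log2 on the E2 3 h arrays and 10.3 ± 0.550 with vehicle (SD, n = 3). That argues against an E2 response as the only difference of these arrays. How much of the 3 h calls came from a batch and how much from E2 cannot be told apart, since no other group shares their title style.

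Interferon-stimulated and luminal genes were higher at 3 h than at 6 h, with adjusted p = 0.658 for each list with an estimated correlation. The interferon median difference of -0.35 lay at percentile 0.41 of 10000 random lists matched on expression, which by the bound set before argues against a general shift of bright genes as the whole cause, but weakly, since random lists lack the correlation of 0.570 estimated among these genes, the highest of the 18 lists. At 3 h against vehicle its median of 0.27 lay at percentile 65.4 (random median 0.25), as such a shift would give, and at 6 h its median of -0.07 lay at percentile 0.02 (random median 0.02), with adjusted p = 0.835 with an estimated correlation and a call lost without any 1 of 4 arrays. Cyclic loess reduced the interferon difference to -0.13 (adjusted p = 0.19), and the luminal difference of -0.32, which quantile normalization took to -0.03 (adjusted p = 0.42), lay at percentile 22.2 (random median -0.28), which is consistent with a general shift, although at 6 h against vehicle the luminal median of -0.013, not called, lay at percentile 1.79 (random median 0.040). Time in culture, E2 and part of such a shift stay open, since no 6 h vehicle was analysed.

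The largest falls at 3 h were not called at 6 h, ST8SIA4 excepted. Of the 5 genes with another probe set, 1 had none called in the same direction and 4 had at least 1. By the test first written, which used that count alone, signal of single probe sets would have been argued against. A condition on size was added after the count was seen: the best other probe set kept a median of 0.179 of the fall, with 0.900 for EGFR, 0.869 for ST8SIA4, 0.179 for TCP11L2, 0.129 for DYNLT2 and 0.108 for CARD16. For EGFR that best other was 1 x_at probe set at -1.46 log2, and its remaining probe sets changed by -0.30 to 0.34 log2. With both conditions, signal of single probe sets and falls of the transcripts cannot be told apart, and either may apply to different genes.

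Other splits of the arrays were compared with the real one. For 3 against 3 arrays the 10 splits are too few for a share under 0.05: as many genes as in the real split were called in 1 split at 3 h (8057, highest other 0), 1 at 6 h (690, highest other 0) and 1 between the times (7311, highest other 0). As many lists were called in 2 splits at 3 h (12, highest other 12), 5 at 6 h (8, highest other 11) and 2 between the times (8, highest other 12). For genes called at both times, 2 of 100 splits of the 9 arrays, the real one among them, gave at least as many as the real one (458), a share under 0.05. Splits that mix the E2 3 h arrays, which stood apart, with other arrays widen the spread within groups and lose calls. This share therefore cannot decide whether the E2 times agree beyond chance. The highest other, 5150, used the 3 E2 3 h arrays as the reference, which points to a structure of those arrays, and the highest without that reference was 246. With the real groups kept and E2 3 h in place of vehicle as the reference, 5854 genes were shared.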

How the results depend on the processing

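Cyclic loess and the fit without the E2 3 h arrays and vehicle replicate 2 were chosen after seeing the data, as were the settings for differences of genes between the times and for control probe sets; the other alternatives were planned. The counts of genes were within 1.5 times the values reported under median centring, quantile normalization, cyclic loess, the mean of probe sets, no x_at or s_at probe sets, every probe set, only the groups compared, an intensity trend and the genes above the median expression. The genes themselves changed more. Of the 8057 called at 3 h, 4540 were also called, in either direction, under quantile normalization and 4777 under cyclic loess. These numbers were 665 and 658 of 690 at 6 h, and 4648 and 4912 of 7311 between the times. At an adjusted p under 0.01, a stricter limit by construction, 5028 genes were called at 3 h, 390 at 6 h, 4312 between the times and 271 at both times. Array weights gave 2294 genes at 6 h and 1338 at both times, and the fit of the groups compared without vehicle replicate 2 gave 307 at 6 h. Lists at 3 h numbered 4 under quantile normalization, 5 among genes above the median, 4 under cyclic loess and 0 by camera with an estimated correlation (1 unadjusted, 15 by fry). Lists at 6 h numbered 1 with an estimated correlation and 3 by fry. Lists between the times numbered 0 under quantile normalization (3 unadjusted, 7 by fry), 1 among genes above the median, 4 without x_at and s_at probe sets, 0 under cyclic loess (3 unadjusted, 6 by fry) and 0 with an estimated correlation (0 unadjusted, 12 by fry).

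Leaving out each array in turn gave 5667 to 8309 genes at 3 h, 395 to 777 at 6 h, 4831 to 7364 between the times and 284 to 525 at both, and 12 to 15, 7 to 9 and 5 to 11 lists. At 6 h the count was 395 and 434 without vehicle replicates 2 and 3, and 430, 445 and 441 without E2 6 h replicates 1 to 3. Genes at both times numbered 284, 296 and 301 without vehicle replicates 2 and 3 and E2 6 h replicate 1. Between the times, genes numbered 4831 without E2 6 h replicate 2, and lists 5 without E2 3 h replicate 2 or 3. Directions turned for RCL1 (-0.025 at 3 h and -0.023 at 6 h) and BHLHE41 (0.086) without x_at and s_at probe sets, ESR1 at 3 h (-0.26 under quantile normalization, -0.22 under cyclic loess), TFF1 at 3 h (-0.24 under cyclic loess), CEBPB between the times (0.093 under quantile normalization, 0.048 under cyclic loess) and DHCR7 between the times (0.013 under quantile normalization). Camera's direction turned for the luminal list at 3 h (-0.018 and -0.060) and the sterol list between the times (0.030 under quantile normalization), both called as deposited. List medians changed sign more often: under quantile normalization for 7 of 18 lists at 3 h, 2 at 6 h and 10 between the times, and under cyclic loess for 6, 2 and 8. Calls were lost, with or without a turn of direction, in 32 settings over 12 named genes at 3 h, in 31 over 8 at 6 h and in 0 between the times for the 8 genes named there, and for lists in 28 over 8, 12 over 3 and 35 over 8. The cause was not tested. The number of arrays limits precision, and without detection calls signal over background is unknown.

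With a replicate block, which assumes paired samples, limma called 7814 genes at 3 h, 628 at 6 h, 7106 between the times and 425 at both. OAS2 was not called at 6 h (-0.30, adjusted p = 0.064), and the sterol list was called at 3 h (adjusted p = 0.049). Whether the numbers pair the samples is not settled. With group means removed, 4 of 9 arrays correlated best with an array of their own number, and some such matches arise without pairing. Arrays of the same number correlated at r = 0.301, 0.106 and 0.042 between vehicle and E2 6 h. Between vehicle and E2 3 h these values were -0.218, -0.229 and -0.236, and between the E2 times 0.083, 0.088 and 0.201.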
